A study of Mus musculus with 4 samples.

How the data were processed

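Gene expression was measured in 4 pooled mouse tissues, each on 1 single-colour array, and all arrays were on 1 slide. According to the labels, RNA was extracted with TRIzol and a Promega kit and labelled with the Agilent Low Input Quick Amp kit. The extraction text of the labels also mentions cerebellum, so markers of that tissue were included among the lists. The intensity values in the deposited scanner files were made by the authors with Agilent Feature Extraction. Per the file headers, the software version was 10.7.1.1 (the processing notes list 9.5.1.1), the background was subtracted, a spatial and a multiplicative detrend were applied, dim spots received surrogate values, and no scaling between arrays was done. The deposited value table of the series also holds intensity, on a linear scale. Its 4 columns share 1 maximum and nearly 1 distribution, which shows a between-array normalization that no header names, and 4460 probes of the arrays are absent from it. Each array had 62976 spots, of which 59305 were not controls. Signals were well above background for 57.0% of these spots in MMA, 59.3% in LLS, 62.9% in LMA and 58.9% in T, and 0 spots were saturated. Spike-in slopes lay between 1.01 and 1.02.

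Probes were named through their RefSeq accessions with a table of current mouse symbols. This named 32475 of 56605 probes, 452 more were named through an older symbol, 11503 kept the symbol in the file and 12175 had none. Positions are those in the file headers (mm9). Flagged spots and 4 probes with no unflagged spot on an array were left out, repeated spots of a probe were averaged, and probes without a symbol were counted but not named. For each gene with more than 1 probe, the probe with the highest mean signal over the 4 arrays was taken, which gave 25669 genes.

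For the main values, log2 of the processed signal was taken and the 75th percentile of the probes on the same array was subtracted. That percentile was a signal of 422 in MMA, 456 in LLS, 507 in LMA and 491 in T. A value not well above background was replaced by the higher of itself and the lowest well-above-background value of its array, so its difference is a lower bound. A gene was compared where its probe was well above background in at least 1 of the pair of tissues. With 1 array per tissue, no test between tissues, SD between replicates or p-value was computed, and genes were counted by size alone, at least 2-fold. The error of a single spot was taken from 291 probes printed 10 times and well above background on all their spots. A count by size does not separate differences between tissues from differences between pools.

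Tissue-specific genes were found with the outlier step of ROKU, the method named in the series design. The values of each gene were standardised by their mean and SD, and outlier tissues were chosen by the AIC statistic of Ueda with at most 1 of 4 tissues as an outlier. The tissue also had to lie at least 2-fold from the nearest other tissue. The Tukey biweight centring of ROKU (c = 5) served only to compute an entropy, which took no part in the calls.

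Gene lists and the rule for naming genes were written before the data were examined. The 20 gene lists covered myogenic regulators, contractile and fusion genes, distal and proximal arch patterning, tooth-forming genes, neural crest, cartilage, bone, tendon and connective tissue, epithelium, taste papillae, the Hedgehog, Wnt, BMP and TGF-beta, and retinoic acid pathways, cell cycle, early embryonic genes of the Lin28 and let-7 axis, Hox genes, ribosomal protein genes, and immediate early and heat shock genes. The 10 marker lists covered endothelial, primitive erythroid, erythroid, macrophage, neuron, Schwann cell, cardiac, pharyngeal endoderm, cerebellum and salivary gland markers. Of 467 entries, 465 were found, as 437 different genes. For each list the median difference was set against 10000 random lists of the same size drawn from 20 expression bins (seed 1), and a median outside the percentiles from 2.5 to 97.5 stands apart from genes of like level. These percentiles describe these arrays and are not p-values. The named genes are, for each comparison, the 10 highest and 10 lowest among genes measured in both tissues and the 3 largest bounds in each direction. For each tissue they are the 6 specifically high and 3 specifically low genes farthest from the nearest other tissue, and any list member could be named. Clone and gene-model names were left out, and results for a pair of list members are not reported here.

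The counting steps were tested on simulated data made from the mean levels of the 4 arrays with a spot SD of 0.1. Among genes with a signal over 100, 0 of 50 genes with a 1.5-fold difference and 50 of 50 with a 2.5-fold difference were called, 48 of the latter as tissue-specific, and 1 of 25469 unchanged genes was called. Apart from the set changes, the simulated arrays differed by spot noise only, without differences between pools or brightness-dependent differences between arrays. The simulation therefore checks the counting steps and gives no rate of false calls in these data. Of the simulated random lists, 4% fell outside the matched range, a share largely set in advance because they were drawn from the same genes.

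The alternatives were quantile normalization, scaling on the median of probes well above background on all arrays, normexp background correction with an offset of 50, the deposited value table, genes well above background on both arrays only, no filter and no floor on dim probes, the mean over all probes of a gene, a 4-fold size rule and, for tissue-specific genes, no AIC step or up to 2 outlier tissues. Cyclic loess between arrays was added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 and R 4.3.3 with limma 3.58.1 were used.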

Results

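RNA from pooled tissue of ICR mouse embryos, an outbred stock, was labelled with Cy3 and hybridised to single-colour Agilent mouse arrays, 1 array per tissue. The 4 tissues were the median mandibular arch at E9.5 (MMA, 12 embryos in the pool), the lateral lingual swellings at E11.5 (LLS, 4 embryos), the lateral mandibular arch at E11.5 (LMA, 4 embryos) and the median tongue at E14.5 (T, 4 embryos). The mandibular arch forms the lower jaw, and the lateral lingual swellings are the outgrowths on its floor that give rise to most of the anterior tongue. Of 25669 genes, 15306 gave a signal well above background in MMA, 15926 in LLS, 16624 in LMA and 16130 in T, and 14301 did so in all 4 tissues.

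There were no replicates, so the number of arrays limits the precision and no difference between tissues has a replicate check. Every gene difference is a difference of log2 signal, the first tissue minus the second, and a difference of 1 is 2-fold. Probes printed 10 times on each array put the SD of a single-spot difference between 0.051 and 0.067 in the 5 comparisons, which covers spot error but not differences between pools. It comes from 291 probes well above background on all their spots, so it does not cover dim values. In LLS minus LMA the log2 error given by Feature Extraction was 0.31 for Shh, 0.34 for Eppk1 and 0.32 for Tac1. Each of these genes was dim in 1 of the tissues, with signals of 26.9 and 23.1 in LMA and 27.9 in LLS. Where the probe of a gene was not well above background in 1 of the tissues, the difference is a lower bound and is written as at least that size or as a bound.

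LLS and LMA, dissected at the same stage, were compared to ask which genes set the tongue-forming outgrowths apart from the lateral arch. Shh, the Hedgehog ligand of oral and lingual epithelium, was 94.0-fold higher in LLS (log2 difference 6.55), and the transcription factor gene Foxa1, known from endoderm-derived epithelium, was 56.9-fold higher (5.83). Its relative Foxa2 was at least 169-fold higher (7.40), since its probe was not well above background in LMA. LMA had the higher levels of the Iroquois homeobox genes Irx2 (-4.86), Irx1 (-4.57) and Irx3 (-4.47), of the arch mesenchyme homeobox genes Msx2 (-3.53) and Msx1 (-3.06), and of the Wnt antagonist gene Dkk1 (-3.14). In all, 610 of the 16998 genes compared were at least 2-fold higher in LLS and 488 at least 2-fold lower, of which 130 and 109 were bounds. These counts depend on the treatment of dim probes, with 1394 higher and 1696 lower without filter and floor and 354 and 202 with normexp background correction. The Shh probe lay on chromosome 5 at 28783456 to 28783515, that of Foxa1 on chromosome 12 at 58641764 to 58641823 and that of Foxa2 on chromosome 2 at 147868669 to 147868728 (mouse build mm9, per the file headers).

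**Figure D1:**
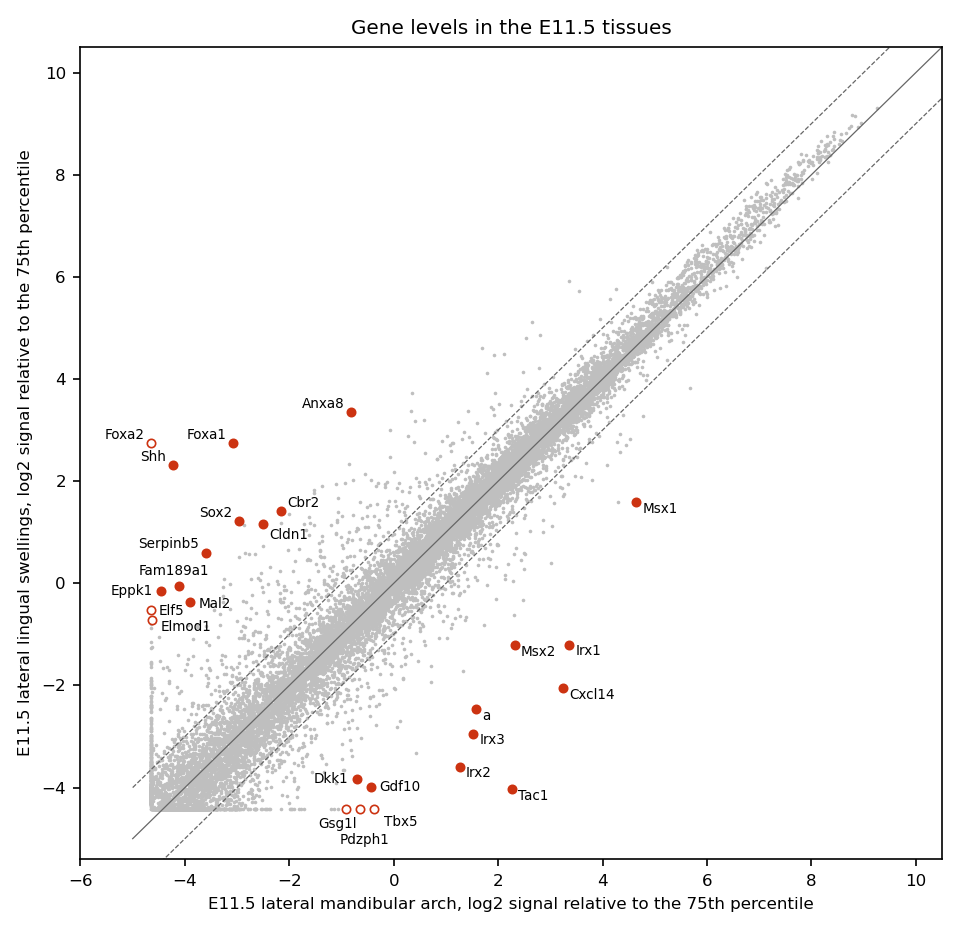
Each grey point is a gene, with its log2 signal relative to the 75th percentile of the array in LMA at E11.5 on the x axis and in LLS at E11.5 on the y axis; the solid line marks equal levels and the dashed lines a 2-fold difference. Red points are the genes named by rule, open where the difference is a bound, and Shh (6.55 above the line of equality) and Tac1 (-6.29, below it) are the farthest from the solid line among those measured in both tissues.

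Among the other genes named for this comparison, higher levels in LLS were found for the epiplakin gene Eppk1 (4.31), the serpin gene Serpinb5 (4.20), the annexin gene Anxa8 (4.18), the transcription factor gene Sox2 (4.18), Fam189a1 (4.07), the tight-junction gene Cldn1 (3.66), the carbonyl reductase gene Cbr2 (3.57) and Mal2 (3.54). Elf5, a transcription factor gene of epithelia, was at least 4.12 higher and Elmod1 at least 3.91 higher. Lower levels in LLS were found for Tac1 (-6.29), which encodes the precursor of substance P, the chemokine gene Cxcl14 (-5.30), the agouti gene a (-4.05) and the BMP-family gene Gdf10 (-3.55), and as bounds for the T-box gene Tbx5 (-4.03), Pdzph1 (-3.78) and Gsg1l (-3.51). The Tac1 and Cxcl14 values rest on the brightest probe, as another probe of Tac1 differed by 0.06 and another of Cxcl14 by 0.10, and the probes of a ranged from -4.10 to -0.53.

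Epithelial genes as a group were higher in LLS: 17 of the 24 compared members were at least 2-fold higher and 0 at least 2-fold lower, with a median of 2.27. The simple-epithelium keratin gene Krt8 (3.38), the claudin genes Cldn6 (3.24) and Cldn7 (3.06) and the E-cadherin gene Cdh1 (2.91) led, while the basal-cell genes Krt14 (0.50) and Krt5 (0.33) stayed within 2-fold and Trp63 was 0.23 by its brightest probe and 2.56 by another. In the Hedgehog list, 7 of 14 members were higher and 2 lower, with a median of 1.05. The pathway targets Ptch1 (1.87), Gli1 (1.66, under 2-fold by another probe) and Hhip (1.32) and the forkhead genes Foxd1 (3.28), Foxf2 (2.56) and Foxf1 (2.40) were higher. The Hedgehog co-receptor genes Gas1 (-1.95) and Cdon (-1.51, under 2-fold by another probe) were lower. The taste papilla list had a median of 0.52, with 5 of 12 members higher and 0 lower, led by Foxa2, Shh, Sox2 and Krt8. Of its 13 genes, 6 also belong to other lists. In the retinoic acid list (median 0.39, 3 of 10 higher and 1 lower) the degrading enzyme gene Cyp26a1 was at least 3.50 higher and the synthesis gene Aldh1a1 2.16 higher. The proximal arch list had a median of 0.28. Pitx1 (2.84-fold) and Lhx8 (2.85-fold) were among the 4 higher, and Dlx5 (-1.86) and Dlx6 (-1.30) were the 2 lower of 14. By direction alone, 7 of its members were higher and 7 lower, and 5 of the 14 belong to other lists as well. Tooth-forming genes had a median of 0.35, with 5 of 15 higher, Pax9 (2.76) and Sp6 (2.45, under 2-fold by another probe) among them, and Msx1 lower. However, that median was -0.04 with no filter and no floor on dim probes, and 10 of the 18 listed genes belong to other lists as well. The medians of these 6 lists lay at percentiles from 99.6 to 100 among 10000 random lists matched on expression.

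Muscle genes were lower in LLS than in LMA. Of 35 contractile and fusion genes, 26 were at least 2-fold lower and 0 higher, with a median of -1.46, including the calcium channel gene Cacna1s (-2.69), the embryonic myosin gene Myh3 (-2.62) and the actin gene Acta1 (-1.81). The myogenic regulators had a median of -0.33, with Myog (-1.49) the 1 member of 15 at least 2-fold lower. Endothelial markers were lower alongside, with a median of -0.88 and 5 of 13 at least 2-fold lower, Erg (-2.24) and Cldn5 (-1.42) among them. Distal arch genes had a median of -1.19, but went both ways: Msx2, Msx1 and Hand1 (-2.24) were among the 6 lower of 12, and Foxf2, Foxf1 and Osr1 (1.26) were the 3 higher. The medians were -0.39 for tendon and connective tissue genes (2 higher and 4 lower of 25; Ogn -2.28, Scx -1.73), -0.61 for the Wnt list (2 higher and 3 lower of 18; Rspo2 -2.20), -0.48 for the BMP and TGF-beta list (0 higher and 2 lower of 17; Tgfb2 -1.06) and -0.69 for the Hox genes (0 higher and 4 lower of 9; Hoxb3 -2.70), all at or below percentile 0.17.

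All 24 ribosomal protein genes were higher in LLS by less than 2-fold, with a median of 0.41 (percentile 99.97). This median was 0.14 after cyclic loess and 0.11 with quantile normalization. Immediate early and heat shock genes had a median of 0.29 (percentile 99.6), with Hspb1 (1.41), Klf4 (1.17) and Jun (1.13) the 3 members of 16 at least 2-fold higher. Macrophage markers (-0.16), neuron markers (0.15) and Schwann cell markers (0.28) had medians inside the range of the matched lists. So did pharyngeal endoderm markers (-0.05), of which 3 of 7 were at least 2-fold higher, Foxa1 and Foxa2 among them, and 1 lower. Among 373 of the called genes that had another usable probe, 92.2% showed the same direction by the other probes and 45.0% also a 2-fold difference. Counting differences of at least 4-fold left 182 genes higher and 73 lower.

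LLS was next compared with MMA, from E9.5 to E11.5, and both stage and dissected structure differ between them. Osr1, an odd-skipped transcription factor gene of arch mesenchyme, was 154-fold higher in LLS (7.27), the basal keratin gene Krt5 65.1-fold higher (6.02) and the homeobox gene Gsc 45.3-fold higher (5.50). Hic1, which encodes a transcriptional repressor, was at least 224-fold higher (7.81). Lower in LLS were Lin28a (-6.44), which encodes a blocker of let-7 microRNA maturation, Wfikkn1 (-6.79), the protogenin gene Prtg (-5.55), the nuclear receptor gene Nr6a1 (-4.51) and Fgf8 (-4.48), a growth factor gene of early oral epithelium. At least 2-fold differences were found for 1597 genes higher in LLS and 925 lower of 16423, of which 361 and 150 were bounds. The Osr1 probe lay on chromosome 12 at 9586475 to 9586534 and the Lin28a probe on chromosome 4 at 133559245 to 133559304 (mm9).

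The other genes named as higher in LLS were Islr (6.07), Pgm5 (5.88), Scrn1 (5.35), Cldn1 (5.10), the aldehyde dehydrogenase gene Aldh1a7 (4.82), the proenkephalin gene Penk (4.71) and the troponin gene Tnnt1 (4.60), with Fibin (at least 7.62) and Slitrk6 (at least 6.83). Those lower were Hopx (-5.62), the cartilage link protein gene Hapln1 (-4.90), Mogat2 (-4.66), Msx2 (-4.63) and Stard8 (-4.50), and as bounds Dlx4 (-4.42), Gbx2 (-3.74) and Chrna6 (-3.55). Another probe of Stard8 differed by -0.20.

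Genes of muscle were higher in LLS than in MMA: 8 of 14 myogenic regulators (median 2.16) and 24 of 32 contractile genes (median 1.70) were at least 2-fold higher, and 0 and 1 lower. Myog was at least 5.82 higher, Myod1 at least 4.17 and Pax3 at least 4.06, and the myosin light chain gene Myl1 was 4.26 higher. Tendon and connective tissue genes had a median of 2.12 with 16 of 24 higher and 1 lower, such as Thbs4 (at least 4.67), Dcn (3.95) and Scx (3.03). Macrophage markers were higher in LLS as well (median 1.87, 10 of 13), and endothelial markers lower (median -0.95, 3 of 13), as were cell cycle genes (median -0.55, 0 of 28 by 2-fold). The early embryonic list was lower, with a median of -1.15 and 7 of 14 members at least 2-fold lower, led by Lin28a, Lin28b (-3.98) and the DNA methyltransferase gene Dnmt3b (-1.96). In the retinoic acid list (median 1.27, 5 of 10 higher and 1 lower) the synthesis enzyme gene Aldh1a2 was at least 6.75 higher and Cyp26b1 4.46 higher. Distal arch genes had 6 members higher and 3 lower of 12 (median 1.19), with Alx4 (3.52) against Msx1 (-3.13) and Prrx2 (-2.83). Proximal arch genes had 2 higher and 5 lower of 14, with a median of -0.22 inside the matched range (percentile 16.9). Medians were 0.55 for neural crest genes (Sox10 2.69, Sox9 -1.76), 0.71 for Schwann cell markers (4 of 8 higher), 0.49 for epithelial genes (Krt15 4.18, Krt18 -1.62), 0.58 for the Hedgehog list (Foxd1 3.50), 0.78 for the Wnt list (Wif1 3.48, Dkk1 -3.61) and 0.53 for cardiac markers (Myh6 1.92, Myl7 -2.68), all at or above percentile 97.9. Cyclic loess moved the median of all genes in this comparison by 0.12, and counting differences of at least 4-fold left 532 genes higher and 143 lower. Of 966 called genes with another usable probe, 93.8% had the same direction and 50.5% also a 2-fold difference by the other probes.

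T and LLS were compared from the E11.5 swellings to the E14.5 tongue, and the dissected structure differs as well as the stage. All 36 contractile and fusion genes were at least 2-fold higher in T, with a median of 5.79 (55.5-fold). The myosin light chain gene Myl4 was 320-fold higher (8.32), the calsequestrin gene Casq2 219-fold higher (7.78), the actin gene Acta1 128-fold higher and the caveolin gene Cav3 at least 675-fold higher (9.40). The embryonic globin genes Hbb-bh1 (-7.59) and Hba-x (-5.86) were lower in T, as were Igdcc3 (-5.12) and Lin28b (-4.24), both known from early embryonic tissue. At least 2-fold differences were found for 2154 genes higher in T and 1023 lower of 16978, of which 642 and 183 were bounds. The Myl4 probe lay on chromosome 11 at 104448441 to 104448500 and the Hbb-bh1 probe on chromosome 7 at 110990209 to 110990268 (mm9).

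Further genes named as higher in T were Mylpf (7.54), Tceal7 (7.52), the sarcolipin gene Sln (7.51), the troponin genes Tnnc2 (7.36) and Tnnt3 (7.24), Itgb1bp2 (6.99) and Myh3 (6.93), with the muscle cytochrome oxidase gene Cox6a2 (at least 9.33) and the myomesin gene Myom2 (at least 512-fold). Another probe of Mylpf differed by -0.20. Further genes lower in T were the collagen gene Col9a1 (-4.24), Smoc1 (-4.15), Car14 (-4.13), Foxc2 (-3.90), Pcp2 (-3.86) and Dusp9 (-3.81), and as bounds Nr1h5 (-5.46), Mogat2 (-4.84) and Alx1 (-4.10). Another probe of Nr1h5 differed by -0.23.

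Of 16 myogenic regulators, 9 were higher in T and 3 lower, with a median of 1.26: Myf6 was at least 5.44 higher and Myog 2.99 higher, while the progenitor gene Pax3 (-3.28), Tcf21 (-1.80) and Six4 (-1.20) were lower. Tendon and connective tissue genes had a median of 1.34 with 14 of 25 higher, such as Ogn (5.42), Thbs4 (4.50) and Dcn (3.81). Epithelial genes had a median of 1.22 with 14 higher and 3 lower of 25, and here the keratin genes of stratified epithelium Krt17 (6.10), Krt14 (5.36) and Krt5 (5.34) were higher and Cldn6 (-1.81) and Cldn7 (-1.03) lower. Arch patterning genes were lower, 12 of 12 in the distal list (median -2.63; Alx4 -3.78, Osr1 -3.09) and 8 of 14 in the proximal list, with 1 higher (median -1.54; Gsc -3.44, Dlx2 -2.92). All 28 cell cycle genes were lower in T, 8 of them by at least 2-fold, with a median of -0.87, and the early embryonic list had a median of -0.89 (Mycn -2.66, Hmga2 -2.37). Beside these groups, markers of other cell types were higher in T: macrophages (median 1.23, 9 of 13), Schwann cells (1.08, 6 of 10; Fabp7 3.26), neurons (0.93, 6 of 13 with 3 lower; Stmn2 3.15) and pharyngeal endoderm (1.35, 4 of 7 with 1 lower; Foxa2 1.42).

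The 3 primitive erythroid markers had a median of -5.86 in this comparison. In the other erythroid list (median -1.06, 3 higher and 6 lower of 12) the adult globin genes Hbb-b2 (2.34) and Hbb-b1 (2.28) were higher and the erythroid regulator gene Klf1 (-2.48) lower. Immediate early and heat shock genes had a median of 1.23 with 9 of 16 higher (Klf4 3.11, Egr1 2.65, Hspa1b 2.22). The Hedgehog list had a median of -0.70 (3 higher and 5 lower of 14), with Foxf1 (-2.89), Foxd1 (-2.63) and Shh (-1.51) lower, and the retinoic acid list a median of -1.03 (3 higher and 5 lower of 10), with Aldh1a2 (-2.88) lower and Aldh1a3 (4.84) and Cyp26a1 (3.19) higher. Tooth-forming genes had a median of -0.56 (3 higher and 5 lower of 15), with Wnt10a (3.99) and Pax9 (2.63) higher and Barx1 (-2.49) lower. The taste papilla list had a median of 0.79 (4 higher and 1 lower of 12) and the Wnt list one of -0.37 (2 higher and 4 lower of 18). Cyclic loess moved the median of all genes in this comparison by 0.16, and counting differences of at least 4-fold left 932 genes higher and 186 lower. Of 1097 called genes with another usable probe, 93.1% had the same direction and 61.3% also a 2-fold difference by the other probes.

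T was also compared with MMA, over the whole span from E9.5 to E14.5. Krt5 was 2637-fold higher in T (11.36), the myosin light chain gene Myl1 1571-fold higher (10.62), the keratin gene Krt6a 1494-fold higher (10.54), the troponin gene Tnnc2 at least 4067-fold higher (11.99) and Myh3 at least 3024-fold higher (11.56). Lower in T were Igdcc3 (-8.84), Lin28b (-8.22), Hbb-bh1 (-8.21), Prtg (-8.07) and Lin28a (-6.83), and as bounds Mogat2 (-9.50), Msx2 (-7.62) and Cited4 (-6.23). At least 2-fold differences were found for 3066 genes higher in T and 2355 lower of 16897, of which 1039 and 246 were bounds. The Krt5 probe lay on chromosome 15 at 101537514 to 101537573 (mm9).

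The remaining genes named as higher in T were Acta1 (9.89), Tceal7 (9.75), Myl4 (9.68), Myh8 (9.35), Mylpf (9.01), Tnni2 (8.63) and the cardiac actin gene Actc1 (8.18), with Sln (at least 11.09), and those lower were Wfikkn1 (-7.05), Hba-x (-6.41), Car14 (-5.62), Msx1 (-5.45) and Dusp9 (-5.25). Another probe of Mylpf differed by -0.40. All 36 contractile genes were at least 2-fold higher (median 6.89), as were 11 of 16 myogenic regulators (3.15, 2 lower), 20 of 25 tendon and connective tissue genes (3.58), 14 of 25 epithelial genes (2.38, 3 lower) and 7 of 10 in the retinoic acid list (2.05, 2 lower). The early embryonic list had a median of -2.10 with 12 of 14 lower, cell cycle genes -1.32 with 20 of 28 lower, proximal arch genes -2.51 with 8 of 13 lower and 2 higher, and distal arch genes -1.14 with 7 of 12 lower and 2 higher. Immediate early and heat shock genes had a median of 1.66 with 8 of 15 higher and 1 lower, and the taste papilla list one of 1.04. Markers of other cell types moved too, with medians of 3.38 for macrophages, 2.90 for Schwann cells, 1.96 for neurons, 1.35 for pharyngeal endoderm, -6.41 for primitive erythroid cells, -1.39 for other erythroid markers and -1.08 for endothelium. The brightest 10% of genes measured in both tissues had a median of -0.40 and the dimmest 10% one of 0.07. After cyclic loess the median of all genes moved by 0.28, and 73.2% of the genes past 2-fold were higher in T in place of 56.6%. Among genes well above background in both tissues the share was 49.0%, 2027 higher and 2109 lower. Counting differences of at least 4-fold left 1518 genes higher and 367 lower.

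**Figure D2:**
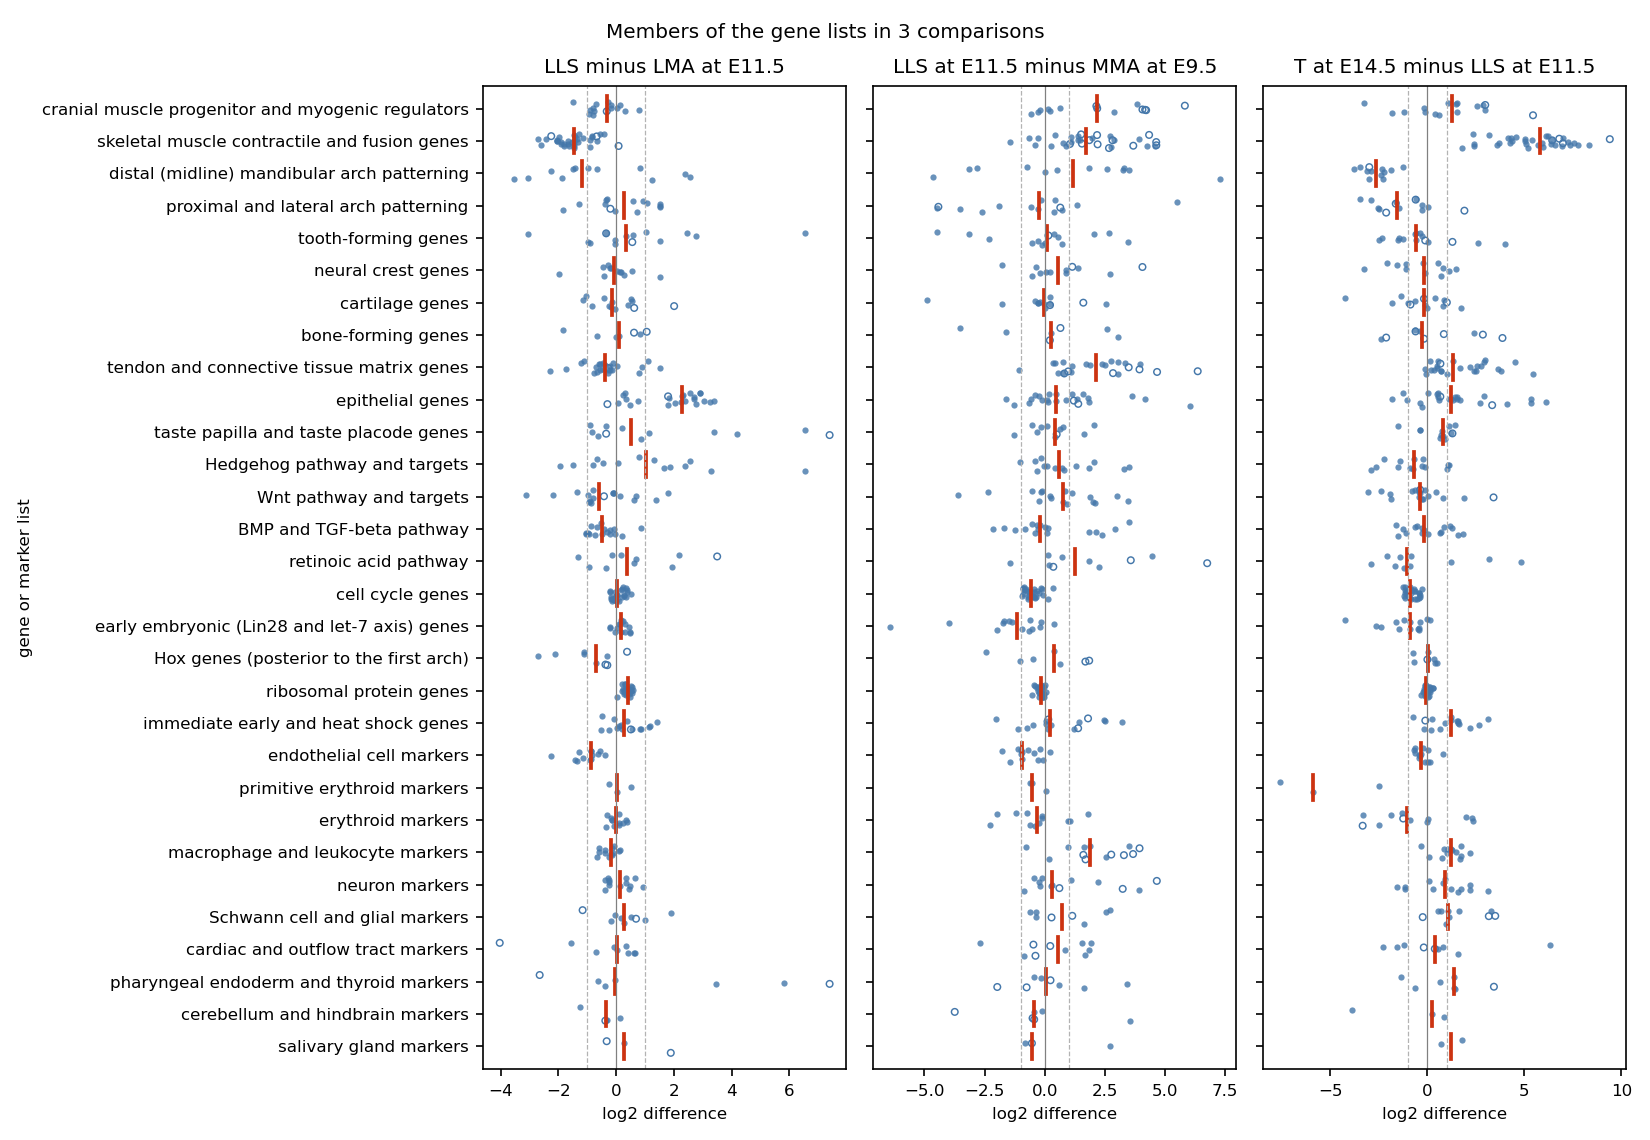
The x axis of each panel is the log2 difference and each line of points is a gene list, for LLS minus LMA, LLS minus MMA and T minus LLS. Each point is a member gene, filled where measured in both tissues and open where a bound, the red bar is the list median and the dashed lines mark 2-fold; the contractile genes have medians of -1.46, 1.70 and 5.79 in the 3 panels.

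LMA was compared with MMA as well, and stage and region both differ. Islr, which encodes an immunoglobulin-domain protein with leucine-rich repeats, was 128-fold higher in LMA, Myl1 72.3-fold higher (6.18), Osr1 64.5-fold higher (6.01) and the muscle regulator gene Myog at least 159-fold higher (7.31). Lower in LMA were Wfikkn1 (-6.56), Lin28a (-6.21), Krt8 (-4.64) and Shh (-4.49), and as a bound Foxa2 (-5.79). At least 2-fold differences were found for 1805 genes higher in LMA and 1226 lower of 16994, of which 448 and 173 were bounds.

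The remaining genes named as higher in LMA were Scrn1 (6.03), Tac1 (5.94), Pgm5 (5.88), Gsc (5.83), Krt5 (5.69), Tspan11 (5.47) and Rgcc (5.46), with Hic1 (at least 7.61) and Myh3 (at least 7.25). Those lower were Nr6a1 (-5.47), the endocytic receptor gene Lrp2 (-5.11), Hopx (-5.01), Prtg (-4.90), Sp6 (-4.77) and Mrap (-4.37), with Car4 (-5.05) and Afp (-5.03) as bounds. Other probes gave -0.23 for Tac1, 0.77 for Myh3 and -0.64 for Lrp2. Contractile genes had a median of 3.16 with 30 of 35 higher, myogenic regulators 2.10 with 10 of 15 higher, tendon and connective tissue genes 1.99 with 19 of 25 higher and neural crest genes 0.86 with 5 of 12 higher and 2 lower. Distal arch genes had a median of 1.08 (6 of 12 higher, 2 lower), the retinoic acid list 0.81, the Hox genes 0.70, the Wnt list 0.57, the BMP and TGF-beta list 0.29, Schwann cell markers 0.98 (3 of 8 higher, 1 lower) and cardiac markers 0.68 (4 of 10 higher, 2 lower). Macrophage markers were higher alongside (median 2.27, 11 of 13), and endothelial markers had a median of 0.30 inside the matched range, which was -0.06 by the mean over all probes. Epithelial genes had a median of -0.91 with 10 of 23 lower and 2 higher, and the medians were -0.61 for the taste papilla list, -0.97 for proximal arch genes, -0.68 for cell cycle genes, -1.27 for the early embryonic list and -0.53 for pharyngeal endoderm markers (Foxe1 -2.87, Foxa1 -2.43). All 24 ribosomal protein genes were lower in LMA, with a median of -0.58 at percentile 1.53. The brightest 10% of genes measured in both tissues had a median of -0.40. The ribosomal list median was -0.03 both after cyclic loess and with quantile normalization. Cyclic loess moved the median of all genes in this comparison by 0.13, and counting differences of at least 4-fold left 613 genes higher and 250 lower. Of 1262 called genes with another usable probe, 90.5% had the same direction and 49.3% also a 2-fold difference by the other probes.

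The stated aim of the series design was to find tissue-specific genes with the ROKU method, and the same idea was applied to all 4 tissues. MMA and T were each the only tissue of their stage, so stage and tissue cannot be told apart in their calls. LLS and LMA shared a stage, and a gene alike in both could be called for neither. The sizes of the counts depend on this choice of tissues. T had the most specifically high genes, 1441, or 672 among genes well above background on all arrays. The 1441 were led by the muscle genes Cox8b (at least 8.29 above the nearest other tissue), Csrp3 (8.23), Myom2 (7.92) and Cox6a2 (7.55), with S100a14 (at least 7.80) and Arhgap36 (at least 7.47). Of the 36 contractile genes 30 were specifically high in T, as were 11 of 26 epithelial genes. The 456 genes specifically low in T were led by Hbb-bh1 (7.08 below the nearest other tissue), Hba-x (5.86) and Igdcc3 (4.99) and included 6 of 12 distal arch genes. MMA had 447 specifically high genes, led by Wfikkn1 (6.56), Lin28a (6.21), Prtg (4.90), Nr6a1 (4.38), Mrap (4.37) and Fgf8 (4.14), and 755 specifically low ones, led by Hic1 (at least 7.38), Col6a3 (at least 6.36) and Islr (6.07). Another probe of Col6a3 was well above background in MMA.

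LMA had 121 specifically high genes, led by a (4.05), Tbx5 (3.56), Pdzph1 (at least 3.56), Irx2 (3.36), Cxcl14 (3.36) and Irx1 (3.33), and 153 specifically low ones, led by Foxa2 (at least 5.79), Shh (4.49) and Sox2 (3.55) and including 9 of 26 epithelial genes. LLS, which shared its stage with LMA, had the fewest, 55 high and 16 low. Its high count was 20 among genes well above background on all arrays, and its counts were 211 and 159 with no filter and no floor. Its high genes were led by the forkhead gene Foxl1 (at least 3.33), Fpr-rs3 (at least 2.64), Foxd1 (2.63), Colec10 (2.54), Fendrr (2.51), a long noncoding RNA gene beside Foxf1, and Vrtn (at least 2.35), and the forkhead genes Foxf1 and Foxf2 were also among them. Its low genes were led by Vgll2 (3.99-fold), Kcnj12 (at least 3.99-fold) and Pax1 (at least 3.92-fold). In total, 3444 of 17869 genes were specific to a tissue by this rule, 2064 high and 1380 low, and at a distance of at least 4-fold the high and low counts were 694 and 71 for T, 67 and 262 for MMA, 24 and 45 for LMA, and 13 and 0 for LLS.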

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

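Cyclic loess and the tests on genes in the same range of brightness, on mesenchyme genes and on the spread of epithelial genes were chosen only after the results were seen. Among the genes named by rule or listed, 11 differed from MMA by at least 2-fold in opposite directions in LLS and in LMA, 5 of them among the 437 listed genes, and 21 of all genes did so. This opposition was not tested, since each tissue had 1 array. The difference between LLS and LMA was 6.55 for Shh (LLS 2.06 and LMA -4.49 relative to MMA), 5.83 for Foxa1 (3.40 and -2.43) and at least 7.40 for Foxa2 (1.61 and -5.79 as a bound). It was 2.91 for the E-cadherin gene Cdh1 (1.12 and -1.79) and 2.55 for Perp (1.34 and -1.21), a desmosome gene. Eppk1 differed by 4.31 (2.06 and -2.25), Mal2 by 3.54 (1.55 and -1.99) and Elmod1 by at least 3.91 (2.28 and -1.63 as a bound). The opposite pattern, lower in LLS and higher in LMA, was found for Irx1 at -4.57 (-1.24 and 3.33), Irx2 at -4.86 (-1.50 and 3.36) and Cxcl14 at -5.30 (-1.95 and 3.36), where another probe of Cxcl14 differed by 0.10.

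Epithelial genes were higher in LLS than in LMA, with a median of 2.27. Cyclic loess left the median at 2.19, which argues against a brightness-dependent difference between the arrays as the whole cause. A larger share of the same epithelium in the LLS pool stays open: it would raise members alike, and the middle 50% of the 22 members measured in both tissues spanned 1.72 (95% bootstrap interval 0.55 to 2.53), but probes of the same gene already spanned 0.81 (0.65 to 1.08) over 140 genes and the intervals overlap. Both intervals treat the genes as independent and do not cover differences between pools. A different kind of epithelium in the tissues also stays open, untested.

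Contractile muscle genes were lower in LLS than in LMA, with a median of -1.46. Dilution of all other RNA by epithelium in the LLS pool would lower mesenchyme genes by about as much. However, 20 general mesenchyme genes had a median of -0.33 (95% bootstrap interval -0.40 to -0.18), and 1 of them was at least 2-fold lower. The interval treats these genes as independent and does not cover differences between pools. Cyclic loess left the muscle median at -1.43. Both values argue against these explanations as the whole cause, and a smaller share of muscle cells, earlier stages of the same cells and chance differences between pools stay open, untested.

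All 24 ribosomal protein genes were higher in LLS than in LMA, with a median of 0.41. A brightness-dependent difference between the arrays may be part of the cause, as 132 other genes in the same range of brightness had a median of 0.16 (95% bootstrap interval 0.13 to 0.19). The list stood 0.25 above these genes (0.13 to 0.33). However, these genes were taken from the whole range of the list and not matched on brightness within it, and the interval treats the list members as independent. Brightness as the whole cause therefore stays open. After cyclic loess, a fit in which the list itself took part, the median was 0.14, and it was 0.11 with quantile normalization. A biological difference between the tissues stays open, untested.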

How the results depend on the processing

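Cyclic loess was chosen only after the results were seen, and the other 10 alternatives were planned. No paired analysis and no leaving out of replicates was possible because each tissue had 1 array. All 1999 alternative values of the 255 gene differences kept their direction, with 18 no longer 2-fold, and so did all 269 of the 36 distances of tissue-specific genes, with 2 no longer 2-fold. These genes were named by size on the same arrays or quoted in the text, so that choice largely set the kept direction in advance. Of 1192 alternative values of the 149 list medians, 1122 kept their sign and 51 were no longer 2-fold. Among medians outside the matched range, 1 reversed, that of the tooth-forming genes in LLS minus LMA, -0.038 with no filter and no floor in place of 0.35. Of the 178 alternative counts of genes, 126 stayed within 1.5 times the main count, among them all those with quantile normalization, scaling on the median, the deposited table, the mean over probes and both other outlier rules. In the values that follow, higher and lower counts are given for LLS minus LMA, LLS minus MMA, T minus LLS, T minus MMA and LMA minus MMA, and specifically high and low counts for MMA, LLS, LMA and T.

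A 4-fold size rule, which by construction counts fewer genes, gave 182 and 73, 532 and 143, 932 and 186, 1518 and 367, and 613 and 250, with specific counts of 67 and 262, 13 and 0, 24 and 45, and 694 and 71. With no filter and no floor on dim probes, which by construction adds dim genes and lets differences exceed their bounds (not separated), the counts were 1394 and 1696 for LLS minus LMA (45.1% of calls higher in place of 55.6%), 2675 and 1945 for LLS minus MMA, 3329 and 1896 for T minus LLS, and 3152 and 2147 for LMA minus MMA. Specific counts were then 735 high in MMA, 211 high and 159 low in LLS, 417 high and 258 low in LMA, and 712 low in T. Normexp background correction, whose offset of 50 shrinks dim differences by construction, gave 354 and 202 for LLS minus LMA, 956 and 537 for LLS minus MMA, 1385 and 586 for T minus LLS, and 1101 and 738 for LMA minus MMA. Specific counts were then 425 low in MMA, 27 high and 3 low in LLS, 64 high and 84 low in LMA, and 249 low in T. Genes well above background on all arrays compared, a smaller set by construction, gave 2027 higher and 2109 lower in T minus MMA (49.0% of calls higher in place of 56.6%) and specifically high counts of 20 in LLS, 53 in LMA and 672 in T. Cyclic loess gave 1391 lower in T minus MMA and 289 specifically low in T. Among genes measured in both tissues of T minus MMA, the median was 0.07 in the dimmest 10% and -0.40 in the brightest 10%. Cyclic loess removes a trend of this kind. How much of the change in counts this trend explains was not tested. Signal near background limits the counts beside the lack of replicates, as bounds made up 130 of 610 and 109 of 488 calls in LLS minus LMA and 1039 of 3066 and 246 of 2355 in T minus MMA.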

Other observations

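Cartilage and bone genes, which build the jaw beside the tongue, had medians inside the matched range between LLS and LMA. Cartilage genes had a median of -0.13 (0.04 by the mean over all probes), with Acan at least 2.01 higher in LLS and Hapln1 (-1.15, another probe -0.76) and Col9a2 (-1.03) lower, and bone genes a median of 0.11 (-0.01 among genes measured in both tissues). From LLS to T the bone list had a median of -0.26 inside the matched range (percentile 4.17), with 3 higher and 2 lower of 10. The bone matrix genes Ibsp (at least 3.87) and Spp1 (at least 2.86) were among those higher. The cartilage list had a median of -0.15 inside the matched range, with 2 higher and 4 lower of 14, the collagen gene Col2a1 (-1.82) among those lower. Over the whole span from MMA to T the BMP and TGF-beta list had a median of 0.45 (percentile 98.7). Of its 17 members, 7 were at least 2-fold higher and 6 lower. The ligand genes Tgfb3 (4.20), Tgfb2 (3.21) and Bmp2 (3.02) were among those higher. Among those lower were the ligand gene Bmp4, which was specifically low in T, and the BMP target genes Bambi (-3.66) and Id1 (-2.26). Among the cardiac markers, the troponin gene Tnnt2, also known from embryonic skeletal muscle, was 8.16 higher in T than in MMA (3.73 by another probe), and Myl7 was -2.11. The genes of this paragraph were chosen after their values were seen.

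Of the 15 cerebellum and hindbrain markers, 9 were well above background in no tissue. The 4 compared between LLS and LMA had a median of -0.35 (0.21 with no filter and no floor), and Pcp2, known from Purkinje cells, was 3.53 higher in LLS and 4.80 higher in LMA than in MMA. Of the 7 salivary gland markers, 4 were well above background in no tissue, and the 3 compared between LLS and LMA had a median of 0.28 with Cldn10 at least 1.89 higher in LLS. Of 14 Hox genes posterior to the first arch, 5 were well above background in no tissue. Probes without a gene symbol also differed: of 5706 compared between LLS and MMA, 233 were at least 2-fold higher in LLS and 254 lower, and of 5770 compared between T and LLS, 363 were higher in T and 324 lower.

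Several listed genes named in the results rest on their brightest probe, as another probe of the same gene differed by less than 2-fold. Between LLS and LMA another probe gave 0.07 for Hoxb3, -0.05 for Sp6, -0.26 for Cdon, 0.44 for Gli1, -0.52 for Rspo2 and -0.89 for Myh3. Between LLS and MMA this was 0.67 for Myl1 and -0.64 for Dnmt3b, between LMA and MMA -0.73 for Foxe1, and between T and LLS -0.22 for Hmga2 and 0.41 for Stmn2.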
